A study of Mus musculus with 30 samples.

How the data were processed

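MicroRNA (miRNA) levels were measured in heart sections containing both ventricles from female C57BL/6 mice. The mice had received 1 intratracheal instillation of 162 µg Printex 90, a commercial carbon black made of nanosized particles, or of vehicle, and were killed 1, 3 or 28 days later. Per the labels, the vehicle was saline with acellular bronchoalveolar lavage fluid, RNA was taken with a mirVana kit, and each mouse gave its own RNA. The series text states 6 mice per group; 30 samples were held here, from 4 vehicle and 6 Printex 90 mice on day 1, 6 and 5 on day 3, and 4 and 5 on day 28. Each array was hybridised with RNA labelled in 1 colour, 8 arrays to a slide.

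Per the file headers, the authors' scans were quantified with Feature Extraction 10.7.3.1. The deposited scanner files hold background-subtracted and detrended signal intensity on a linear scale for each spot, with flags for spots well above background, saturated or outlying within their probe. The file of 1 Printex 90 mouse from day 3, replicate 3, lists miRNA names without a signal, so 29 arrays entered every model. A deposited series value table gives log2 intensity per miRNA for all 30 samples. On 29 arrays its values ranked miRNAs as the median pixel signal of each miRNA's spots did (Spearman correlation of at least 0.995), without background subtraction, and its column medians lay between 5.78 and 5.82. How its columns were brought to 1 scale is not stated, and it was used only as an alternative.

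The arrays carried 45440 spots, with 2889 probes for 1079 mouse and 57 viral miRNAs. Processed signal was averaged over the spots of a probe, leaving out control spots and outlying spots. A probe counted as detected on an array when a share of at least 0.5 of its spots was well above background. Arrays were scaled on the 75th percentile of the 418 probes detected on all arrays. Signals below the lowest detected one, 16.9 (4.08 on the log2 scale), were raised to it, and values were taken to log2. A miRNA's value was the mean over its probes detected on at least 4 arrays of at least 1 group, which left 306 miRNAs and 621 probes. Names are those printed on the array, matched to miRNA arms by name; no genome coordinates are given, since no reference table was used.

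The share of spots well above background ran from 18.4% to 27.5% per array, and between 231 and 339 mouse miRNAs were detected. The 75th percentile before scaling differed 2.34-fold between the brightest and the dimmest array. No spot was saturated (0 spots), and outlying spots made up between 2.85% and 9.32%. At the floor lay 1.88% of the values. The median residual SD was 0.27 on the log2 scale, and the number of arrays limits the precision.

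Groups were fitted together in limma 3.58.1 under R 4.3.3, with 1 mean per group and moderated variances. Two-sided contrasts compared Printex 90 with vehicle on each day and as the mean of the days, the exposure difference between days, and days within vehicle mice, 10 comparisons in all. Adjusted p-values followed Benjamini and Hochberg over the 306 miRNAs, with a threshold of 0.05. The fit on 29 arrays takes the place of the 30 planned. Sets of miRNAs were tested with camera at a preset correlation of 0.01, adjusted over lists and comparisons together, and again with an estimated correlation and with fry. Sets with fewer than 3 tested members were given as values only.

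The 16 lists, fixed before the data were examined, covered muscle and cardiomyocyte, fibroblast and matrix, inflammation-induced, leukocyte, endothelial, smooth muscle, red blood cell, hypoxia, p53-responsive and other-tissue markers, the let-7, miR-17, miR-15/16 and miR-30 families, and the Dlk1-Dio3 and Sfmbt2 clusters. The tests, the alternatives and the rule for naming miRNAs were also fixed then. Among the tested fibroblast and matrix miRNAs were miR-29a, miR-29a*, miR-29b, miR-29c and miR-29c*. The others were miR-21, miR-214, miR-199a-3p, miR-199a-5p and miR-199b*. For exposure, the rule named up to 15 miRNAs per direction past the threshold, or, if fewer than 10 passed, the 5 with the smallest p in each direction as values that did not pass. It added up to 4 members per list with the smallest p and 16 fixed miRNAs (miR-1a, miR-133a, miR-208a, miR-499, miR-21, miR-146a, miR-146b, miR-155, miR-223, miR-142-3p, miR-126-3p, miR-451, miR-122, miR-135b, miR-210 and miR-34a). For time and for differences between days it named up to 10 past the threshold and 3 otherwise.

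Alternatives changed 1 choice at a time, except that normexp also changed the pixel signal and the series value table differed in signal, background subtraction and scaling at once: the 75th percentile over all probes, quantile normalization, no scaling, normexp background correction with an offset of 50, the software's total gene signal, the brightest probe, the series value table, a floor at the 5th percentile, no filter, detection on all 29 arrays, slide as a fixed or random block, values within slides, only the groups compared, array weights, trend and robust variances, thresholds, and leaving out each array in turn. The normexp alternative used median in place of mean pixel signal, the column held. With no filter, 652 of 1079 miRNAs lay at the floor on every array and were left out, which left 427. The array weights estimated by restricted maximum likelihood did not converge. Chosen after the data were seen were weights estimated gene by gene, leaving out the 4 dimmest arrays, leaving out arrays of groups not compared for miRNAs that passed, a covariate for the share of spots well above background, and the time contrasts in Printex 90 mice and over both treatments. A shift of the median of all miRNAs by scaling is given in the report.

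The pipeline was tested on simulated data in which 60 miRNAs per run were given 1.5-, 2- or 3-fold changes in 20 runs. On day 1 the fit recovered 59.8%, 83.3% and 96.0% of these, with a mean of 1.15 other calls per run. The mean of other calls per run was 7.40 for exposure on day 3 and 5.30 for vehicle day 28 against day 1, where 64.8%, 78.0% and 93.8% were recovered. Beside at most 60 changed miRNAs per run, both means exceed the share of false calls that the adjusted threshold aims for. In the mean over days it recovered 84.5%, 97.0% and 99.3%. Changing 60 of 306 miRNAs at once makes the adjusted threshold easier to pass than when few change. Recovery with few changed was not tested, so these percentages may overstate it for comparisons in which no miRNA passed. Correlations across arrays used values with group means removed and 100000 permutations within groups. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and, in R, the data.table package (version 1.17.8), and plots with matplotlib 3.10.9.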

Results

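Hearts of 29 female mice gave signals on miRNA arrays, from 4 vehicle and 6 Printex 90 mice on day 1, 6 and 4 on day 3, and 4 and 5 on day 28. Of 1079 mouse miRNAs on the array, 373 were detected on at least 1 array and 211 on all 29. In vehicle mice on day 1 the muscle miRNA miR-1a had a mean log2 signal of 16.00 ± 0.15 (SD, n = 4), miR-133b 14.94 ± 0.10 and miR-133a 13.84 ± 0.12. Of the miRNAs carried by myosin genes, miR-499 was at 11.20 ± 0.06, miR-208a-3p at 8.92 ± 0.22 and miR-208b at 5.37 ± 0.15. Signals of different probes do not rank the amounts of their miRNAs. Of 33 markers of liver, pancreas, brain, epithelium and cilia on the array, 2 were tested: miR-122 of liver, detected on 26 arrays, and miR-128, detected on 29. Red cell miR-451 stood at 13.73 ± 0.24, endothelial miR-126-3p at 13.54 ± 0.09 and miR-29a, which targets collagen transcripts, at 12.52 ± 0.08. The share of spots well above background averaged 25.7% ± 1.34 (SD, n = 4) in vehicle and 23.6% ± 3.35 (n = 6) in Printex 90 mice on day 1, 23.5% ± 3.58 (n = 6) and 24.2% ± 1.45 (n = 4) on day 3, and 24.5% ± 1.81 (n = 4) and 24.7% ± 0.631 (n = 5) on day 28.

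The first comparison asked whether carbon black placed in the airways was followed by other miRNA levels in the heart after 1 day. No tested miRNA differed between 6 Printex 90 and 4 vehicle mice past the threshold. Cardiac muscle miRNAs were close to vehicle, at log2 differences (Printex 90 minus vehicle) of 0.03 ± 0.07 (SE) for miR-1a, −0.10 ± 0.10 for miR-133a, −0.12 ± 0.11 for miR-208a-3p and −0.12 ± 0.15 for miR-499. Red cell miRNAs had higher values in most exposed mice: miR-451 0.47 ± 0.24 and miR-144* 0.57 ± 0.26, each above the vehicle mean in 5 of 6 mice. Below vehicle in 6 of 6 were miR-204, at −0.26 ± 0.12, and miR-146a, a brake on innate immune signalling, at −0.31 ± 0.17. These 4 did not pass (adjusted p = 0.742 by limma).

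By limma, 0 of 306 miRNAs passed on day 1, and 2 had an unadjusted p under 0.05, where chance alone gives 15.3; with slide in the fit the smallest adjusted p was 0.748. Other values with the smallest p were 0.36 ± 0.19 for miR-3085-3p, 0.42 ± 0.24 for miR-144, 0.17 ± 0.10 for miR-25, −0.49 ± 0.28 for miR-329, −0.67 ± 0.39 for miR-7b* and −0.45 ± 0.27 for miR-211. Inflammation-induced miRNAs stood lower in 4 of 5 (median −0.20, but −0.08 with slide as a block; adjusted p = 0.464), with miR-155 at −0.08 ± 0.09, miR-132 at −0.25 ± 0.17 and miR-21 at 0.05 ± 0.11, and miR-146b and miR-135b were detected on 0 arrays. Leukocyte miRNAs went both ways, with a median of −0.07 but a mean of 0.03 (adjusted p = 0.637): miR-142-3p, made in blood cells, was at 0.27 ± 0.18 and myeloid miR-223 at −0.07 ± 0.10. Endothelial miR-126-3p was at −0.04 ± 0.08, hypoxia-induced miR-210 at 0.04 ± 0.09, p53-induced miR-34a at −0.05 ± 0.08, and liver miR-122 at 0.63 ± 0.73. Within slides miR-451 ranged from 0.16 to 0.88, miR-144* from 0.16 to 1.04, miR-146a from −0.63 to 0.03 and miR-204 from −0.47 to 0.03. With slide as a block these were 0.49, 0.59, −0.31 and −0.25.

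As sets on day 1, 42 of 42 miRNAs of the Sfmbt2 intron list had lower values in exposed mice, miR-467d* (−0.44 ± 0.30) among them. The list, named for a large rodent cluster, was drawn up by how miRNA names begin, and the locus of each member was not checked. Its median was −0.43 (camera adjusted p = 2.24e-09, but adjusted p = 0.634 with an estimated correlation). Without Printex 90 day 1 replicate 4, the lowest of all arrays, the median was −0.18. In this comparison exposed mice also had a lower share of spots well above background, and the cluster's median was −0.11 with that share as a covariate; it was −0.37 with slide as a block and −0.82 to 0.05 within slides. Of 4 red cell miRNAs the 3 from the miR-144 and miR-451 locus had higher values and miR-486* was at 0.00 ± 0.08 (median 0.44; adjusted p = 4.31e-04, but adjusted p = 0.303 with an estimated correlation). The median was 0.46 with slide as a block and 0.14 to 0.91 within slides. The miR-17 clusters, which promote cell growth, were higher in 9 of 10 (median 0.11, camera adjusted p = 2.26e-05, but 0.350 with an estimated correlation). Within slides they were at 0.05 to 0.10. With no scaling their median was −0.08, where that of all tested miRNAs was lower still. Fibroblast and matrix miRNAs were higher in 9 of 10 (median 0.05, camera adjusted p = 0.037, but 0.634 with an estimated correlation). Their median was −0.14 with no scaling and −0.02 with total gene signal, where that of all tested miRNAs was lower still. That last call ended without vehicle replicate 2 (adjusted p = 0.0711) or 4 (0.109), without Printex 90 replicate 4 (0.132) or 5 (0.311), without the 4 dimmest arrays (0.412) and with the brightness covariate (0.321). Its median was 0.02 without vehicle replicate 2, 0.03 without vehicle replicate 4, 0.07 without Printex 90 replicate 2 and 0.01 without Printex 90 replicate 5. Muscle miRNAs were lower in 8 of 10 (median −0.09, adjusted p = 0.822), endothelial in 8 of 10 (−0.01, 0.880), p53-responsive in 4 of 4 (−0.07, 0.576), the miR-15/16 family in 5 of 8 (−0.09, 0.847) and Dlk1-Dio3 miRNAs in 7 of 8 (−0.15, 0.606). The let-7 family was higher in 10 of 13 (median 0.03 but mean −0.01, adjusted p = 0.212), the miR-30 family in 6 of 11 (0.02, 0.0847), and both smooth muscle miRNAs were higher (0.11).

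On day 3 no tested miRNA differed between 4 Printex 90 and 6 vehicle mice past the threshold, in the comparison of the same question 2 days later. The muscle miRNAs were again near vehicle: miR-1a at 0.07 ± 0.07, miR-133a at −0.03 ± 0.10, miR-208a-3p at 0.02 ± 0.11 and miR-499 at 0.00 ± 0.15. The smallest p was that of miR-10b, a miRNA of the Hox gene clusters, at 0.70 ± 0.29 and above the vehicle mean in 4 of 4 exposed mice (adjusted p = 0.999 by limma). Its relative miR-10a was at 0.65 ± 0.38. The red cell miR-451, higher by value on day 1, was at −0.18 ± 0.24. It was at −0.45 without Printex 90 replicate 2, and between −0.10 and −0.06 without Printex 90 replicate 1, 4 or 5 or vehicle replicate 5.

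By limma, 0 of 306 passed on day 3 and 1 had an unadjusted p under 0.05; 0 passed with slide as a block, and 1 with array weights that did not converge. Further values were 0.23 ± 0.11 for miR-30d*, 0.68 ± 0.40 for miR-504*, 0.72 ± 0.42 for miR-1927, −0.35 ± 0.19 for miR-5109, −0.26 ± 0.15 for miR-2137, −0.29 ± 0.18 for miR-2861, −0.37 ± 0.25 for miR-5126 and −0.39 ± 0.27 for miR-5105. Inflammation miRNAs were higher in 4 of 5 (median 0.07, adjusted p = 0.682), with miR-146a at 0.11 ± 0.17, miR-155 at 0.08 ± 0.09 and miR-21 at 0.07 ± 0.11. Leukocyte miRNAs were higher in 3 of 5, with miR-223 at 0.03 ± 0.10 and miR-142-3p at −0.03 ± 0.18. Values were −0.04 ± 0.08 for miR-126-3p, 0.07 ± 0.09 for miR-210, −0.02 ± 0.08 for miR-34a and −0.82 ± 0.73 for miR-122. With slide as a block miR-10b was at 0.73, and within slides as low as −0.04.

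The miR-30 family was higher by value in 10 of 11 on day 3 (median 0.08, camera adjusted p = 0.037; adjusted p = 0.609 with an estimated correlation) but at −0.01 when scaled on all probes and at −0.00 in the series value table. Fibroblast and matrix miRNAs were lower in 9 of 10 (median −0.06, camera adjusted p = 0.0472, but 0.634 with an estimated correlation). With no scaling their median was 0.06, where that of all tested miRNAs was higher still. The call on miR-30 ended with slide as a block (0.0508) and without vehicle day 3 replicates 2 (0.108), 5 (0.695) or 6 (0.0601), Printex 90 day 3 replicates 2 (0.139) or 4 (0.269), or Printex 90 day 1 replicate 4 (0.0522). The call on fibroblast miRNAs ended with slide as a block (0.0642), the brightness covariate (0.168) and without the 4 dimmest arrays (0.118). It also ended without vehicle day 3 replicates 3 (0.0736), 5 (0.796) or 6 (0.0992), vehicle day 1 replicates 1 (0.051), 2 (0.0506) or 4 (0.0618), Printex 90 day 3 replicates 1 (0.128), 4 (0.112) or 5 (0.118), Printex 90 day 1 replicates 3 (0.0509), 4 (0.0522), 5 (0.072) or 6 (0.0564), or Printex 90 day 28 replicate 2 (0.0651). Its median was −0.10 without vehicle day 3 replicates 2 or 4 and 0.02 without replicate 5, and that of miR-30 was 0.05 without Printex 90 day 3 replicate 4. Sfmbt2 miRNAs were higher in 39 of 42 (median 0.12, adjusted p = 0.179), let-7 in 12 of 13 (0.06, 0.154), muscle in 7 of 10 (0.02, 0.880) and Dlk1-Dio3 in 5 of 8 (0.10, 0.847). Lower were 3 of 4 red cell miRNAs (−0.16, adjusted p = 0.176), 7 of 10 endothelial (median −0.02 but mean 0.00, 0.475), 3 of 4 p53-responsive (median −0.02 but mean 0.02, 0.815) and both smooth muscle miRNAs (−0.09). The miR-17 clusters (0.00, 0.789) and the miR-15/16 family (−0.00, 0.838) had no common direction.

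On day 28, which asked about a late state, no tested miRNA differed between 5 Printex 90 and 4 vehicle mice past the threshold. The smallest p belonged to miR-208a-3p, carried by the cardiac alpha-myosin gene, which was lower by value in 5 of 5 exposed mice at −0.25 ± 0.12 (adjusted p = 0.906 by limma). Also below the vehicle mean in 5 of 5 were miR-101c at −0.15 ± 0.07, miR-101a at −0.12 ± 0.07 and miR-29b at −0.16 ± 0.09, the last known to repress collagen transcripts. Red cell miR-451 was at 0.42 ± 0.25, with 1 of the 5 mice level with the vehicle mean (13.51 each), and miR-144* at 0.49 ± 0.27. Without Printex 90 replicate 2 they were at 0.25 and 0.30. None of these 6 passed.

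By limma, 0 of 306 passed on day 28, 1 had an unadjusted p under 0.05, and 0 passed with slide as a block. Further values were −0.18 ± 0.11 for miR-29c, 0.38 ± 0.23 for miR-3102-3p.2, 0.25 ± 0.16 for let-7f-1* and 0.26 ± 0.17 for miR-3072*. Muscle miR-1a was at −0.03 ± 0.08, miR-133a at −0.08 ± 0.10 and miR-499 at −0.06 ± 0.15, and miR-208b was detected on 0 of 5 and 0 of 4 arrays, so no fold is given. Inflammation and blood cell miRNAs were at 0.10 ± 0.17 (miR-146a), 0.08 ± 0.09 (miR-155), 0.00 ± 0.12 (miR-21), −0.06 ± 0.10 (miR-223) and 0.27 ± 0.19 (miR-142-3p). Values were −0.01 ± 0.08 for miR-126-3p, 0.00 ± 0.09 for miR-210, 0.04 ± 0.08 for miR-34a and −0.51 ± 0.76 for miR-122. With slide as a block miR-208a-3p was at −0.22, miR-101c at −0.14, miR-29b at −0.16 and miR-451 at 0.47. Within slides they ranged from −0.39 to −0.00, −0.23 to −0.10, −0.26 to −0.06 and −0.06 to 0.89.

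Among sets on day 28, 42 of 42 Sfmbt2 miRNAs had higher values (median 0.38, camera adjusted p = 1.94e-10; adjusted p = 0.634 with an estimated correlation), 0.34 with the brightness covariate, 0.42 with slide as a block and 0.20 to 0.55 within slides. Without vehicle day 28 replicate 3 the median was 0.22. Fibroblast and matrix miRNAs were lower in 9 of 10 (median −0.12, adjusted p = 0.00119; adjusted p = 0.472 with an estimated correlation), −0.11 with slide as a block and −0.29 to 0.01 within slides, and the call ended without vehicle day 28 replicate 4 (median −0.03, adjusted p = 0.189). The miR-30 family was lower in 10 of 11 (median −0.07, adjusted p = 0.0266; adjusted p = 0.570 with an estimated correlation), −0.09 with slide as a block and −0.06 to 0.02 within slides. That call ended without vehicle day 28 replicates 1 (0.121) or 2 (0.0807) and without Printex 90 day 28 replicates 2 (0.250) or 5 (0.0872). Its median was −0.04 without vehicle replicate 2 or Printex 90 replicate 2 and −0.05 without Printex 90 replicate 4. Muscle miRNAs were lower in 8 of 10 (−0.07, adjusted p = 0.0601), endothelial in 10 of 10 (−0.04, 0.057) and both smooth muscle miRNAs were lower (−0.04). Higher values were seen in 3 of 4 red cell (0.38, adjusted p = 0.154), 3 of 5 leukocyte (0.08, 0.677), 3 of 5 inflammation (0.00, 0.938), 7 of 10 miR-17 (0.02, 0.815), 6 of 8 miR-15/16 (0.02, 0.822), 7 of 13 let-7 (0.01, 0.871), 2 of 4 p53-responsive (0.01, 0.880) and 5 of 8 Dlk1-Dio3 miRNAs (0.09, 0.991).

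**Figure D1:**
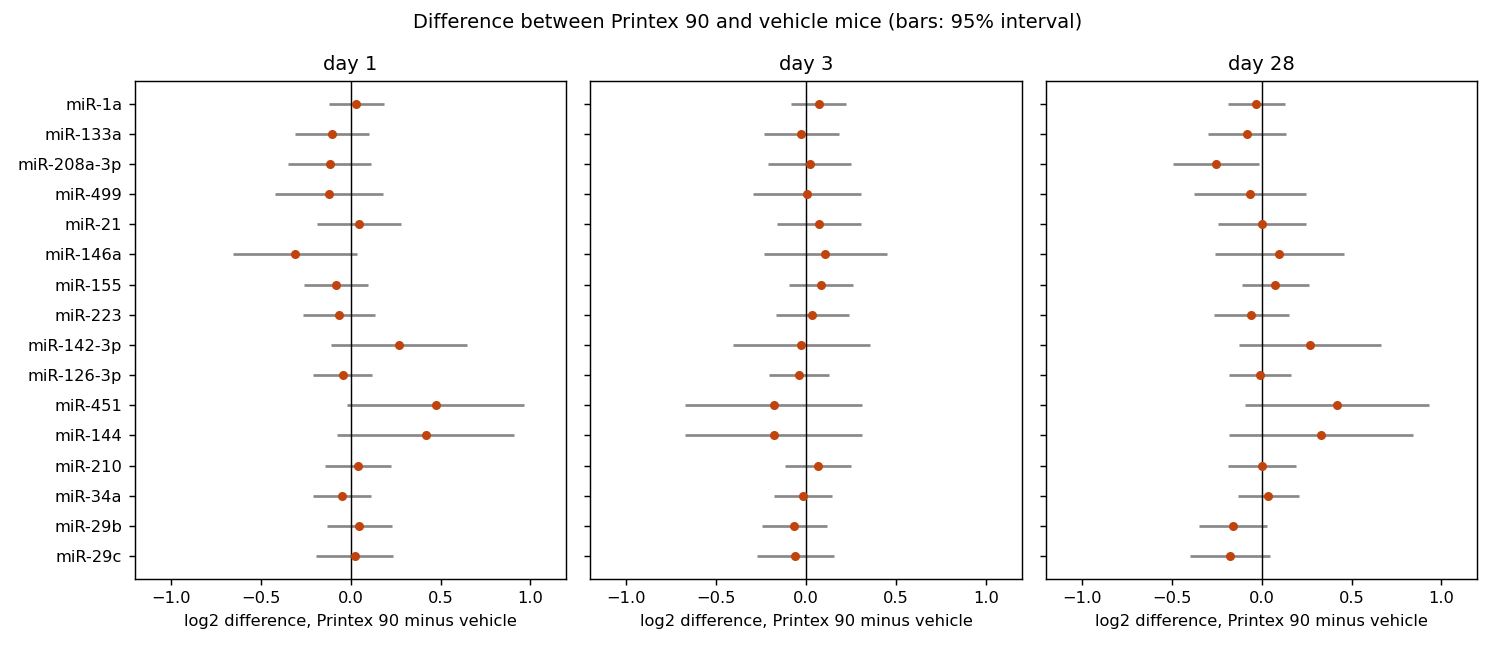
Log2 difference between Printex 90 and vehicle hearts (horizontal axis) for 16 miRNAs on days 1, 3 and 28, with 95% confidence intervals from limma as bars. None of the differences passed the adjusted threshold of 0.05, and miR-1a stayed at 0.03, 0.07 and −0.03.

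**Figure D2:**
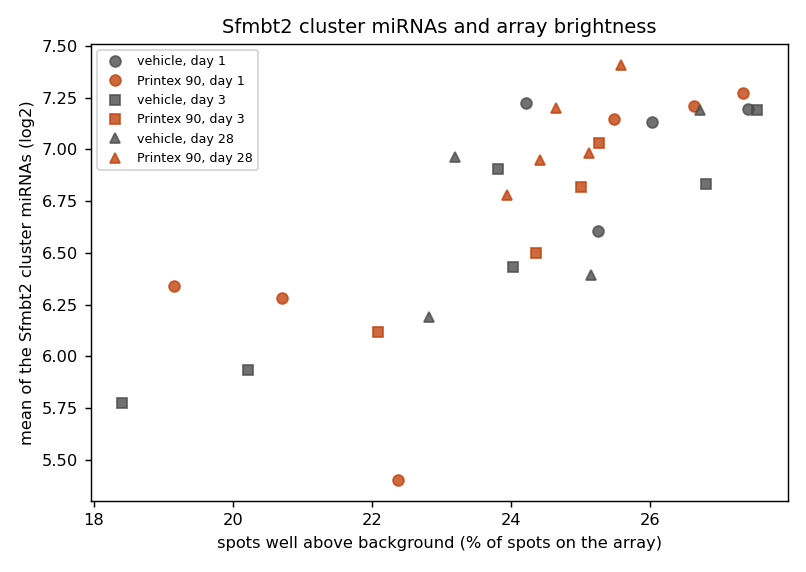
Mean log2 signal of the 42 Sfmbt2 cluster miRNAs (vertical axis) against the percent of spots well above background (horizontal axis), 1 point per array, coloured by treatment. The 29 list means ran from 5.40 to 7.41 over a share of spots from 18.4% to 27.5%. That share counts the spots of these miRNAs too.

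Averaged over the 3 days, again no tested miRNA differed between Printex 90 and vehicle past the threshold. Among blood and heart miRNAs the smallest p belonged to values of 0.30 ± 0.15 for miR-144*, 0.24 ± 0.14 for miR-451 and −0.12 ± 0.07 for miR-208a-3p (adjusted p = 0.994 by limma for each). Muscle miR-1a was at 0.02 ± 0.04, miR-133a at −0.07 ± 0.06 and miR-499 at −0.06 ± 0.09. The inflammation miRNAs miR-21 (0.04 ± 0.07), miR-146a (−0.03 ± 0.10) and miR-155 (0.03 ± 0.05) were as close.

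By limma, 0 of 306 passed in the mean over days and 0 had an unadjusted p under 0.05, with 0 also with slide as a block. The 95% interval lay within 2-fold for 302 miRNAs and within 1.5-fold for 292. On single days fewer intervals were so narrow. Within 2-fold lay 229 on day 1, 287 on day 3 and 237 on day 28, and within 1.5-fold 175, 186 and 178. Other values were 0.13 ± 0.08 for miR-15b, 0.17 ± 0.11 for miR-142-3p, 0.09 ± 0.06 for miR-25, −0.10 ± 0.06 for miR-362-3p, −0.16 ± 0.10 for miR-494, −0.20 ± 0.14 for miR-697, −0.03 ± 0.06 for miR-223, −0.03 ± 0.05 for miR-126-3p, 0.04 ± 0.05 for miR-210 and −0.01 ± 0.05 for miR-34a. Liver miR-122 was at −0.24 ± 0.43. Red cell miRNAs were higher in 3 of 4 (median 0.21, camera adjusted p = 0.00125; adjusted p = 0.303 with an estimated correlation), a call that ended without Printex 90 day 3 replicate 2 (median 0.12, adjusted p = 0.153) or Printex 90 day 1 replicate 4 (0.0539) and with the brightness covariate (0.0651). The miR-17 clusters were higher in 9 of 10 (median 0.04, adjusted p = 8.36e-04; adjusted p = 0.490 with an estimated correlation) but at −0.01 with no scaling and in the series value table. That call ended without Printex 90 day 28 replicate 2 (0.0663) or day 1 replicate 4 (0.0821). The let-7 family was higher in 11 of 13 (median 0.04, adjusted p = 0.0266; adjusted p = 0.637 with an estimated correlation) but at −0.01 with no scaling. Its call ended with slide as a block (0.0958) and the brightness covariate (0.193). It also ended without vehicle replicates 1 (0.139) or 2 (0.138) of day 1, 1 (0.0735), 2 (0.0528) or 3 (0.0623) of day 3, or 1 (0.217), 2 (0.0779) or 3 (0.1) of day 28, and without Printex 90 replicates 4 of day 1 (0.183), 5 of day 3 (0.184) or 5 of day 28 (0.147). Its median was 0.02 without vehicle replicates 1 or 3 of day 28 or 4 of day 3, and 0.06 without vehicle replicate 4 of day 28 or Printex 90 replicate 2 of day 3.

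In the exposure comparisons 0 members of any list passed, over all miRNAs or adjusted over the list alone. Scaling moved the median difference of all tested miRNAs, which was −0.07 on day 1, 0.11 when scaled on all probes, −0.24 with no scaling and −0.17 with total gene signal, and 0.04 with normexp. On day 3 it was 0.03, and 0.13 with no scaling. On day 28 it was 0.01, and −0.16 when scaled on all probes. In vehicle mice between days 1 and 28 it was −0.05, against 0.13 when scaled on all probes and −0.21 with no scaling. Between days 3 and 28 it was 0.10, against −0.03 when scaled on all probes, and between days 1 and 3 it was −0.04, against 0.27 when scaled on all probes, −0.26 with no scaling and 0.07 in the series value table. Set tests compare a list with the other miRNAs, so list medians stand relative to these. A list median that changes sign with scaling therefore does not by itself go against a call.

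Whether the exposure difference itself changed between days was asked in 3 further contrasts, and no tested miRNA passed. Between days 1 and 3, miR-10b (0.93 ± 0.40), miR-204 (0.34 ± 0.16) and miR-335-5p (0.51 ± 0.26) had the smallest p upward, and the red cell miRNAs miR-144* (−0.71 ± 0.37), miR-451 (−0.65 ± 0.34) and miR-144 (−0.60 ± 0.34) downward (adjusted p = 0.735 by limma). Between days 1 and 28 they were miR-3112* (0.76 ± 0.37), miR-3102-3p.2 (0.66 ± 0.32) and miR-467d* (0.83 ± 0.43), with miR-31 (−0.36 ± 0.15), miR-101c (−0.20 ± 0.10) and miR-29b (−0.21 ± 0.13) below (adjusted p = 0.484). Between days 3 and 28 miR-10b was at −0.95 ± 0.41, miR-450a at −0.22 ± 0.12, miR-208a-3p at −0.27 ± 0.16, miR-451 at 0.60 ± 0.35, miR-144* at 0.63 ± 0.38 and miR-144 at 0.51 ± 0.34 (adjusted p = 0.982). By limma the counts were 0, 0 and 0 of 306, with 2, 3 and 1 at an unadjusted p under 0.05, and 0 with slide as a block.

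In vehicle mice, hearts on day 28 differed from those on day 1 in 6 miRNAs, a comparison that shows how levels moved over the study without particles. The myosin miRNA miR-208b, carried by the beta-myosin gene, fell: it was detected on 4 of 4 arrays on day 1 (mean log2 signal 5.37) and on 0 of 4 on day 28. Against the lowest signal detected on each array it was at least 1.77-fold lower, a bound on means without a sampling error. Its adjusted p of 3.08e-05 by limma is for values with the floor applied, not for the bound. The size depends on how signals are processed: fitted values were −3.23 ± 0.57 with total gene signal, −0.57 ± 0.15 with a higher floor, −0.42 ± 0.09 in the series value table and −0.28 ± 0.13 with normexp. Of 5 tested miRNAs of the miR-29 family, which represses collagen and other matrix transcripts, 4 rose: miR-29b by 0.54 ± 0.10 (adjusted p = 0.0012), miR-29c by 0.57 ± 0.11 (0.00311), miR-29c* by 0.42 ± 0.09 (0.00771) and miR-29a by 0.51 ± 0.12 (0.0229). The other, miR-29a*, was at 0.47 ± 0.24 (adjusted p = 0.755), named for this comparison after its value was seen. Also higher was miR-31, by 0.45 ± 0.12 (adjusted p = 0.0373). Each of the 6 that passed stood beyond the day 1 mean in 4 of 4 day 28 mice. The alpha-myosin miRNA miR-208a-3p was at 0.07 ± 0.12, outside the naming rule and chosen after its value was seen.

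The count was 6 by limma (5 up, 1 down), with 16 at an unadjusted p under 0.05. With slide as a block miR-208b had an adjusted p of 1.31e-04, with miR-29a at 0.53, miR-29b at 0.54, miR-29c at 0.59, miR-29c* at 0.45 and miR-31 at 0.45, all past the threshold. Within the 3 slides that held both days, miR-208b was detected on 3 of 3 day 1 arrays and 0 of 4 day 28 arrays, so no fold within slides is given. In these slides miR-29a ranged from 0.35 to 0.79, miR-29b from 0.40 to 0.73, miR-29c from 0.40 to 0.83, miR-29c* from 0.33 to 0.62 and miR-31 from 0.15 to 0.81. Of fibroblast and matrix miRNAs, 9 of 10 were higher and 4 passed, as 4 did adjusted over the list alone. The set had a median of 0.30 (camera adjusted p = 3.80e-08, but 0.303 with an estimated correlation). The 4 past the threshold over all miRNAs were miR-29a, miR-29b, miR-29c and miR-29c*, so the list is not separate evidence from the miR-29 family. The list without its miR-29 members was not tested. Among muscle miRNAs miR-208b alone passed, also adjusted over the list alone, with miR-1a at 0.03 ± 0.08, miR-133a at 0.11 ± 0.11 and miR-499 at 0.20 ± 0.16. The miR-30 family was higher in 9 of 11 (median 0.12, camera adjusted p = 0.0462, but 0.634 with an estimated correlation). With no scaling its median was −0.05, where that of all tested miRNAs was lower still. That call ended without vehicle day 28 replicates 1 (0.104) or 2 (0.0807), vehicle day 1 replicate 4 (0.193), Printex 90 day 28 replicate 2 (0.0565) or Printex 90 day 1 replicates 3 (0.0509) or 6 (0.0511). Sfmbt2 miRNAs were lower in 42 of 42 (median −0.35, adjusted p = 5.74e-05; adjusted p = 0.828 with an estimated correlation), with 24.5% of spots well above background on day 28 against 25.7% on day 1. Without vehicle day 28 replicate 3 that median was −0.18, and the miR-30 median was 0.07 without vehicle day 28 replicate 2 or vehicle day 1 replicate 4. Red cell miRNAs were lower in 3 of 4 (−0.25, adjusted p = 0.789), inflammation miRNAs higher in 4 of 5 (0.03, 0.762), and the smallest p downward after miR-208b were those of miR-301a (−0.26 ± 0.09, adjusted p = 0.294) and miR-5127 (−0.83 ± 0.36).

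Leaving out any 1 of the 29 arrays kept the calls on miR-208b (highest adjusted p = 3.33e-04), miR-29b (0.00865) and miR-29c (0.0295). The call on miR-208b, at −1.27 ± 0.17 as fitted to floor values that give no fold, ended with quantile normalization (−0.92 ± 0.24, adjusted p = 0.0589) and no scaling (−1.24 ± 0.30, 0.083), each with a wider SE. It also ended with normexp (−0.28 ± 0.13, 0.902). Scaled on all probes, miR-29a was at 0.68 ± 0.25, miR-29b at 0.72 ± 0.24, miR-29c at 0.75 ± 0.24, miR-29c* at 0.60 ± 0.23 and miR-31 at 0.63 ± 0.23, larger values with wider SEs that did not pass (adjusted p = 0.581 each). With no scaling they were 0.33 ± 0.25, 0.37 ± 0.24, 0.40 ± 0.26, 0.25 ± 0.23 and 0.28 ± 0.24 (adjusted p = 0.841 each). Fitting only the groups compared ended the calls on miR-29a (0.102), miR-29b (0.0646), miR-29c (0.0910), miR-29c* and miR-31 (0.178 each) at the same differences. The series value table ended those on miR-29a (0.50, adjusted p = 0.0800), miR-29b (0.53, 0.122), miR-29c* (0.33, 0.122) and miR-31 (0.24, 0.396). Quantile normalization ended those on miR-29b (0.36, 0.0589), miR-29c* (0.64, 0.362) and miR-31 (0.55, 0.403), and normexp those on miR-29c* (0.29) and miR-31 (0.24; adjusted p = 0.902 each). The call on miR-31 also ended with total gene signal (0.46, 0.118), a higher floor (0.32, 0.0922), the brightness covariate (0.44, 0.0587), and trend and robust variances (0.0587). The call on miR-29a ended without vehicle day 1 replicates 2 (0.0819), 3 (0.0742) or 4 (0.0672) or day 28 replicate 4 (0.191). The call on miR-29c* ended without day 1 replicate 2 (0.0536) or day 28 replicate 4 (0.0699), and that on miR-31 without day 28 replicates 1 (0.0961), 3 (0.0524) or 4 (0.238) or day 1 replicates 3 (0.206) or 4 (0.223). The count fell from 6 to 3 without vehicle day 28 replicate 4.

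Between days 3 and 28 in vehicle mice, miR-208b fell again and miR-29b rose. Detected on 5 of 6 day 3 and 0 of 4 day 28 arrays, miR-208b was at least 1.54-fold lower by the same bound on means. Its adjusted p of 1.28e-04 by limma is for values with the floor applied. The level of miR-29b was higher by 0.37 ± 0.09 (adjusted p = 0.0409 by limma). Each of these 2 miRNAs stood beyond the day 3 mean in 4 of 4 mice. Close to the threshold were miR-29c at 0.39 ± 0.10 and miR-29c* at 0.32 ± 0.08 (adjusted p = 0.0632 each), and miR-29a* was at 0.29 ± 0.22 (0.892). Red cell miRNAs stood lower by value, with miR-451 at −0.70 ± 0.24 (adjusted p = 0.271) and miR-144 at −0.76 ± 0.24 (0.237).

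The count was 2 by limma, with 22 at an unadjusted p under 0.05. With slide as a block 4 passed: miR-208b (adjusted p = 6.91e-04), miR-29b (0.38), miR-29c (0.42) and miR-29c* (0.36). On the 3 slides that held both days miR-208b was detected on 5 of 5 day 3 and 0 of 4 day 28 arrays, and miR-29b ranged from 0.20 to 0.53. In the fibroblast list 1 miRNA, miR-29b, passed and 4 did adjusted over the list alone. In it 9 of 10 were higher (median 0.19, camera adjusted p = 0.00147, but 0.484 with an estimated correlation). The set's call ended without vehicle day 28 replicate 4 (median 0.10, adjusted p = 0.172), and its median was 0.12 without vehicle day 3 replicate 6. In the red cell list 0 passed and 3 were lower adjusted over the list alone (median −0.71, adjusted p = 6.17e-04; adjusted p = 0.303 with an estimated correlation). The miR-17 clusters were lower in 9 of 10 (median −0.10, adjusted p = 1.14e-05; adjusted p = 0.321 with an estimated correlation), −0.06 without vehicle day 28 replicate 1. The call on miR-208b, fitted at −1.07 ± 0.16, ended with quantile normalization (−0.84 ± 0.22, adjusted p = 0.164), no scaling (−0.84 ± 0.27, 1), normexp (−0.35 ± 0.12, 0.412) and a higher floor (−0.37 ± 0.13, 0.279). With total gene signal it was −2.96 ± 0.52 (0.00222). That on miR-29b held in 14 of 30 settings. It ended when scaled on all probes (0.24, adjusted p = 0.985), with quantile normalization (0.28, 0.164), no scaling (0.43, 1), normexp (0.37, 0.0629), the brightest probe (0.38, 0.0650), the series value table (0.25, 0.989), a higher floor (0.37, 0.0682) and only the groups compared (0.37, 0.227). It also ended without vehicle day 28 replicates 1 (0.112), 3 (0.137) or 4 (0.213), vehicle day 3 replicates 2 (0.143), 4 (0.104) or 6 (0.0733), or the 4 dimmest arrays (0.0969). At the same difference of 0.37 it ended without an array of another group: vehicle day 1 replicates 2 (0.0537) or 3 (0.0553), Printex 90 day 1 replicate 2 (0.0533), day 3 replicates 4 (0.0534) or 5 (0.0531), or day 28 replicates 1 (0.0548) or 2 (0.0504).

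Between days 1 and 3 no tested miRNA of vehicle mice passed. Values with the smallest p were −0.91 ± 0.33 for miR-3473d, −0.65 ± 0.25 for miR-3112*, −0.67 ± 0.29 for miR-10b, 0.24 ± 0.11 for miR-31 and 0.20 ± 0.10 for miR-25, with red cell miR-451 at 0.47 ± 0.24 and miR-208b at −0.20 ± 0.16. By limma 0 of 306 passed and 18 had an unadjusted p under 0.05, with 0 with slide as a block. Array weights called 103, and weights estimated gene by gene 85, of which 83 were lower on day 3, the day with 2 of the 4 dimmest arrays among its vehicle mice. Fibroblast miRNAs were higher in 9 of 10 (median 0.12, camera adjusted p = 6.62e-04, but 0.471 with an estimated correlation). Their median was 0.03 without vehicle day 3 replicate 5. The miR-17 clusters were higher in 9 of 10 (median 0.10, camera adjusted p = 5.48e-04, but 0.472 with an estimated correlation). With no scaling the fibroblast median was −0.12 and the miR-17 median −0.13, where that of all tested miRNAs was lower still. Red cell miRNAs were higher in 3 of 4 (0.44, adjusted p = 0.0135; adjusted p = 0.471 with an estimated correlation), a call that ended without vehicle day 1 replicate 1 (0.079). Sfmbt2 miRNAs were lower in 42 of 42 (−0.54, adjusted p = 2.09e-08; adjusted p = 0.637 with an estimated correlation), with 23.5% of spots well above background on day 3 against 25.7% on day 1.

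**Figure D3:**
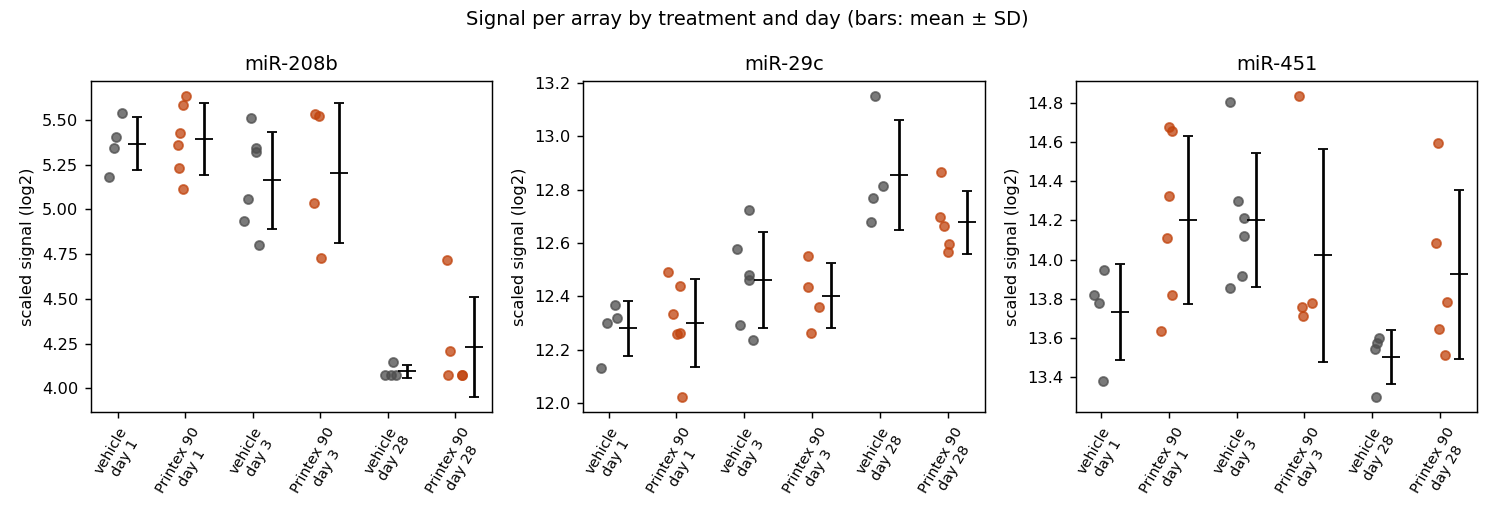
Log2 signal (vertical axis) of miR-208b, miR-29c and miR-451 on each array by group, grey for vehicle and orange for Printex 90, with mean and SD as bars. The highest of 9 day 28 arrays for miR-208b is 4.72 and the lowest of 20 earlier arrays 4.73, while miR-451 spans 13.30 to 14.83 over all arrays.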

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

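Of the tests below, those of brightness, slide and cross-hybridisation on miR-208b, 4 miR-29 miRNAs and miR-31, and the set test with an estimated correlation on the Sfmbt2 cluster, were chosen only after the result was seen. How far a value must exceed its spread to count against an explanation was also tightened after values were seen, which left 6 explanations open that had been counted as excluded or as met. Detection of miR-208b took the place of fitted values at the floor and was compared in 7 versions: 2 had too few arrays to pass at all, and the other 5 passed.

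Vehicle hearts carried less miR-208b and more miR-29a, miR-29b, miR-29c and miR-29c* on day 28 than on day 1. Of the 35 splits of the 8 arrays, 1, the real one, gave as many as 6 miRNAs between days 1 and 28. The highest other split gave 1. This argues against chance for the count but does not exclude it. A share of 1 in 35 is the smallest these splits can give, and the 10 comparisons were split without correction. Of the 6, 4 are miR-29 miRNAs, which need not be independent. For miR-208b, detection on dimmer arrays argues against brightness as the whole cause. Of 6 earlier arrays dimmer than every day 28 array (none from vehicle day 1), 4 had it, against 0 of 9 on day 28 (exact p = 0.011). Of 7 vehicle arrays of days 1 and 3 no brighter than the brightest of day 28, 6 had it (exact p = 0.0152). Detection within slides over both treatments, on 18 of 20 earlier and 0 of 9 day 28 arrays (exact p = 3.64e-05), argues likewise against slide or scan day. For vehicle day 1 alone at that brightness (0.0286) and vehicle mice within slides (0.0104), p was the smallest possible. As miR-208b was picked for this difference, these add little. Versions for vehicle days 1 and 28 within slides or at common brightness were too small to pass. A lower 95% bound of −0.19 for miR-208a-3p argues against cross-hybridisation with miR-208a. For the 4 miR-29 miRNAs, 4 passed with the brightness covariate and 4 with slide as a block, against these as the whole cause, and miR-29c* (adjusted p = 0.00771) argues against cross-hybridisation as the whole rise of miR-29c, while for miR-29a and miR-29b cross-hybridisation with miR-29c stays open, since miR-29a* missed the threshold (0.755). For miR-31 brightness stays open, since its 0.44 ± 0.12 with the covariate missed the threshold (adjusted p = 0.0587) where 0.45 ± 0.12 had passed (0.0373), on a slightly smaller value with a slightly wider SE. A change of the heart with time after instillation, or with age, may account for these levels and stays a hypothesis. Each day had its own mice, so anything else that differed between the days of killing cannot be told apart from time or age. Scaling ended calls on each of them, some at larger values with wider SEs and some at smaller values.

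The 42 Sfmbt2 miRNAs had lower values on day 1 and higher values on day 28 in Printex 90 mice, with 1 array carrying much of each: the medians were −0.18 on day 1 without Printex 90 replicate 4 and 0.22 on day 28 without vehicle replicate 3. Brightness is a candidate explanation on day 1, where the median of −0.43 became −0.11 with the covariate (SE of the list mean 0.23); on day 28, at 0.34 against 0.38, the same SE keeps it open. Across 29 arrays the list mean followed the share of spots well above background (Pearson r = 0.760, permutation p = 3.70e-04, adjusted 9.25e-04; Spearman rho = 0.819, p = 6.00e-05, adjusted 1.50e-04; r = 0.755 without the 2 farthest arrays; 0.770, 0.496, 0.755 and 0.983 within slides 1 to 4; 1 of 5 relations tested). That share counts the spots of these 42 miRNAs too, so the relation is in part built in, and the covariate has the same limit. How large that part is was not tested. A loss of all dim signals stays open: 0 of 10000 random lists of other miRNAs matched on level had so low a median on day 1 (middle 95% from −0.12 to 0.02), but the median of −0.43 lies within 2 SEs of the list mean (0.33). Members that move together between arrays of 1 group are enough to end the call (adjusted p = 0.634 with an estimated correlation), and an effect of the particles stays open and untested apart from these.

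Of the red cell miRNAs, miR-451, miR-144 and miR-144* spread between mice of 1 group and miR-486* little (residual SDs of 0.38, 0.38, 0.42 and 0.11). In Printex 90 mice of day 3 miR-451 ran from 13.71 to 14.83 on the log2 scale. Replicate 2 alone stood at 14.83 there, and the others lay between 13.71 and 13.78. Across arrays miR-451 followed miR-144 of the same locus (r = 0.976, permutation p = 1e-05, the smallest the permutations can give, adjusted 5.00e-05). Their rho was 0.942, and r was 0.971 without the 2 farthest arrays. The amount of blood left in the section may contribute, since the red cell mean rose with the leukocyte mean (r = 0.573, permutation p = 0.00208, adjusted 0.00347; rho = 0.501, p = 0.00596, adjusted 0.00993; r = 0.449 without the 2 farthest arrays; 0.695, 0.884, 0.593 and 0.282 within slides 1 to 4). For miR-451 and miR-486*, from another locus, r was −0.239 (permutation p = 0.274, adjusted 0.294), with a 95% interval from −0.56 to 0.14. Their rho was −0.298 (permutation p = 0.168, adjusted 0.209), and r was −0.163 without the 2 farthest arrays. Whether miR-486* in these heart sections comes from red cells was not tested. This relation therefore cannot decide on the amount of blood, which stays open. Brightness also stays open at r = −0.226 (permutation p = 0.294, adjusted 0.294; rho = −0.157, p = 0.459, adjusted 0.459; r = −0.148 without the 2 farthest arrays), with an interval from −0.55 to 0.15. No biological difference between mice of 1 group was tested.

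For the other counts above 0 the splits do not argue against chance. At an unadjusted p under 0.05, the exposure counts were 2 on day 1 (highest other split 135; 95 of 100 splits gave as many), 1 on day 3 (106; 93) and 1 on day 28 (39; 91). Those for differences between days were 2 for days 1 and 3 (123; 82), 3 for days 1 and 28 (114; 77) and 1 for days 3 and 28 (65; 81). For vehicle days 1 and 3 the count was 18 (108; 23), and with array weights gene by gene, past the adjusted threshold, 85 (123; 15). For vehicle days 3 and 28 it was 2 past the adjusted threshold (72; 5). For the mean over days the count was 0 (117; 100), which every split reaches, so that test says nothing. Over the splits of each comparison, the count at an unadjusted p under 0.05 was weakly to moderately related to the size of the brightness difference (Spearman rho from 0.04 for vehicle days 1 and 28 to 0.47 for exposure on day 3).

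Set tests put the exposure difference of a list apart between days in 11 cases, none of which held with an estimated correlation (smallest adjusted p = 0.303). The median of all miRNAs shifted as well: between days 1 and 28 from 0.03 to −0.32 when scaled on all probes, and between days 1 and 3 from 0.07 to 0.36 with no scaling. Between days 1 and 28 the Sfmbt2 cluster differed by a median of 0.81 (adjusted p = 1.24e-14), fibroblast and matrix miRNAs by −0.16 (8.91e-04), the miR-30 family by −0.09 (0.0142) and the miR-17 clusters by −0.07 (0.0462). The last was 0.06 with no scaling and 0.00 with total gene signal, and miR-30 was 0.04 with no scaling. The miR-30 call ended without vehicle day 28 replicate 1 (0.0503), Printex 90 day 28 replicate 2 (0.0916), Printex 90 day 1 replicate 3 (0.0503) or vehicle day 1 replicate 4 (0.113). The miR-17 call ended without vehicle day 1 replicates 1 (0.117) or 4 (0.0672), vehicle day 28 replicates 3 (0.0766) or 4 (0.138), Printex 90 day 1 replicates 4 (0.132) or 6 (0.104), or Printex 90 day 28 replicates 1 (0.162), 3 (0.0648) or 5 (0.0921). The miR-17 median was −0.05 without Printex 90 day 28 replicate 1, −0.04 without Printex 90 day 1 replicate 6 and −0.02 without vehicle day 28 replicate 4, and the fibroblast median was −0.05 without the last.

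Between days 1 and 3 the Sfmbt2 cluster differed by 0.54 (adjusted p = 5.08e-07; 0.112 with the brightness covariate), red cell miRNAs by −0.63 (8.36e-04), the miR-17 clusters by −0.10 (0.00125) and fibroblast miRNAs by −0.12 (0.00862). With no scaling the miR-17 median was 0.21 and the fibroblast median 0.20, and with total gene signal they were 0.03 and 0.02. The median of all miRNAs with no scaling was higher than both. The fibroblast call ended without Printex 90 day 1 replicate 5 (0.072) or vehicle day 3 replicate 5 (0.094). Its median was −0.01 without the latter and −0.07 without Printex 90 day 3 replicate 2, and the Sfmbt2 median was 0.31 without Printex 90 day 1 replicate 4. Between days 3 and 28 the Sfmbt2 cluster differed by 0.29 (adjusted p = 1.55e-05), miR-30 by −0.11 (1.86e-04) and red cell miRNAs by 0.56 (0.0142). The Sfmbt2 median was 0.14 without vehicle day 3 replicate 1, 0.43 without vehicle day 3 replicate 4, 0.10 without Printex 90 day 3 replicate 2, and 0.46, 0.08 and 0.16 without vehicle day 28 replicates 2, 3 and 4. The red cell call ended with slide as a block (0.0605) and without vehicle day 28 replicates 1 (0.053) or 2 (0.118), Printex 90 day 3 replicates 1 (0.219) or 4 (0.0913), or Printex 90 day 28 replicate 2 (0.082).

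In 162 checks of 27 measures within groups, 16 values stood far from the rest of their group, where chance gives about 1 in 20. In vehicle mice of day 1 they were, in replicate 4, a Sfmbt2 mean of 6.60 (next 7.13) and miR-122 at 4.50 (next 6.32), and in replicate 2 miR-29c* at 6.06. In vehicle mice of day 3 they were 9.32% outlying spots in replicate 6, and miR-208a-3p at 8.42 and miR-34a at 9.22 in replicate 5. In vehicle mice of day 28 they were miR-146a at 6.44 and miR-208b at 4.15, with the others at the floor of 4.08, in replicate 1, and miR-29b at 12.02 in replicate 2. In Printex 90 mice of day 1 they were miR-1a at 15.87 in replicate 2 and miR-21 at 11.24 in replicate 5. Replicate 2 of Printex 90 day 3 had a red cell mean of 9.78 (next 8.98) with miR-451 at 14.83. On Printex 90 day 28, miR-133a was at 14.01 and miR-34a at 9.73 in replicate 5, and miR-208b at 4.72 in replicate 4.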

How the results depend on the processing

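Array weights gene by gene, leaving out the 4 dimmest arrays, the brightness covariate, the time contrasts in other mice and, for miRNAs that passed, leaving out arrays of groups not compared were tested only after the results were seen. The counts of 0 for exposure on day 1 and in the mean over days stayed 0 in every alternative run, and every other exposure or between-day count of 0 did except as follows. Array weights gave 1 on day 3, and an unadjusted p under 0.05 with 1.5-fold gave 1 on day 3, 1 between days 1 and 3, 2 between days 1 and 28 and 1 between days 3 and 28. For vehicle days 1 and 3 the count of 0 became 103 with array weights, 85 with weights gene by gene and 12 by unadjusted p with 1.5-fold. For vehicle days 1 and 28 the 6 became 1 when scaled on all probes, 2 with quantile normalization, 0 with no scaling, 3 with normexp, 2 with the series value table, 11 with either kind of weights, 2 with only the groups compared (1 of them among the 6, on fewer arrays) and 3 by unadjusted p with 1.5-fold. Leaving out 1 array of the groups compared gave 3 to 6, the 3 without vehicle day 28 replicate 4. For vehicle days 3 and 28 the 2 became 1 when scaled on all probes, with the brightest probe, the series value table, only the groups compared or in Printex 90 mice; 0 with quantile normalization, no scaling, normexp or the 5th percentile floor; 4 with either slide block or an adjusted p under 0.1; 5 with total gene signal, no filter or weights gene by gene; and 6 with array weights, unadjusted p with 1.5-fold or over both treatments. Leaving out 1 array of the groups compared gave 1 to 4: 1 without vehicle day 28 replicates 1, 3 or 4 or day 3 replicates 2, 4 or 6, and 4 without day 28 replicate 2 or day 3 replicate 5. Scaled on all probes there were 21 list calls in place of 33, of which 19 were among the 33. Of the 33, 17 stayed with array weights, 19 with weights gene by gene, 20 with quantile normalization, 22 with no scaling, 0 with an estimated correlation and 0 with fry. The cause of these changes was not tested. No direction turned past the threshold. Of values of miRNAs named for passing, 170 stayed, 66 lost the call with the same direction and 14 moved; of those that did not pass, 9710 stayed, 365 moved and 35 passed. With no filter, 652 miRNAs at the floor on every array gave no test. Signal over background limits the dim miRNAs: miR-208b on day 28 lay below detection, so its fold is a bound.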

Other observations

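The time contrasts in Printex 90 mice and over both treatments were chosen only after the vehicle result was seen, as was the choice to name miR-301a in them; miR-1895, outside the naming rule, was named after its value was seen.

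With time, exposed hearts too had less miR-208b and more of some miR-29 members. From day 1 to day 28 in Printex 90 mice, miR-208b fell from a mean of 5.39 with detection on 5 of 6 arrays to below detection on 5 of 5. The fall was at least 1.69-fold by the bound on means, and its adjusted p of 9.94e-06 by limma is for values with the floor applied. There miR-29b rose by 0.33 ± 0.08 (adjusted p = 0.0458) and miR-29c by 0.38 ± 0.10 (0.0498), each above the day 1 mean in 5 of 5 mice, while miR-29a was at 0.35 ± 0.11 (0.151) and miR-31 at 0.09 ± 0.10. From day 3 to day 28 miR-208b fell at least 1.48-fold by that bound, in 5 of 5 mice. With the floor applied its adjusted p by limma was 0.00101. By limma 4 miRNAs passed between days 1 and 28, 1 between days 3 and 28, and 0 between days 1 and 3, where 0 had an unadjusted p under 0.05. For a change of the exposure difference between days, no tested miRNA passed by limma (smallest adjusted p = 0.484 for days 1 and 28). For days 1 and 28 the 95% interval of that change lay within 2-fold for only 194 of 306 miRNAs. A like course in both treatments is therefore not shown.

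A fall of miR-301a, which lies in an intron of Ska2, was seen in Printex 90 mice between days 1 and 28, at −0.35 ± 0.08 (adjusted p = 0.0215 by limma) and in 5 of 5 mice. Part of it rests on day 1 replicate 5, at 7.28 where the other day 1 mice lay between 6.69 and 6.74. The value without that array is not given here. Over both treatments it was at −0.30 ± 0.06 (adjusted p = 0.00154), and miR-1895 at 0.29 ± 0.07 (0.0235). Over both treatments 7 miRNAs passed between days 1 and 28 and 6 between days 3 and 28, with miR-29b at 0.44 ± 0.06 and 0.33 ± 0.06. On the log2 scale the highest of the 9 day 28 arrays had miR-208b at 4.72, and the lowest of the 20 arrays from days 1 and 3 at 4.73.

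Viral miRNAs on the array were tested apart from the mouse miRNAs. Of 57, 10 were detected on at least 1 array, 2 on all arrays, and 9 entered a test. Whether their signals are specific was not tested. By limma 0 of these 9 viral miRNAs passed between Printex 90 and vehicle in any exposure comparison, with 0 at an unadjusted p under 0.05 (smallest adjusted p = 0.540). As no mouse miRNA passed there either, this cannot serve as a check on the exposure comparisons.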
